A study of Drosophila melanogaster with 12 samples.

How the data were processed

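Expression in ovaries of 4 genotypes was measured on 12 Affymetrix Drosophila Genome 2.0 arrays, 3 per genotype. Per the labels, each replicate was about 150 pairs of ovaries from virgin females, from which total RNA was extracted with TRIzol, 50 ng was amplified by single primer isothermal amplification, and the product was biotin-labelled. Tissue, title and protocol name the ovary, while the source name and description name embryos, and the samples are treated here as ovary. The authors deposited intensity values on a linear scale, which the submitters' processing notes credit to GCOS, and every array has a trimmed mean (2% at each end) of 1500. The version and settings of GCOS are not given in the sources used here.

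The array table holds 18952 probe sets, of which 183 are controls, 13647 carry 1 gene (11982 genes), 402 carry several and 4720 carry no symbol. Symbols of 13544 probe sets were updated through their gene number. Background was taken as the 95th percentile of 27 bacterial control probe sets (61.97). The number of arrays limits the precision.

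Intensity was transformed as log2(signal + 16). Array medians differed by up to 0.393 on the log2 scale, above the limit of 0.1, so the arrays were quantile normalized. Probe sets above the 40th percentile of the array in at least 3 of the 12 arrays were kept (12618), and each gene was represented by its single-gene probe set with the highest mean, which left 9105 genes. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom), and a gene was called at an adjusted p (Benjamini and Hochberg) below 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 6 pairs of groups and the average of the sterile against the average of the fertile groups were compared, and genes called the same way in all 4 sterile against fertile pairs were counted.

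Whether replicates with the same number are paired was checked from the correlations of the arrays after removal of group means. The 18 pairs with the same number had correlations of -0.1535 to 0.0979, none above 0.1, and 3 of 12 arrays were closest to an array of their own number, so the arrays were not treated as paired. The method was tested on simulated data for 9105 genes with 200 changed genes, in 5 runs. It recovered 50% of changes of 0.5 on the log2 scale, 78.8% of changes of 1, 95.6% of changes of 2 and 99.6% of changes of 3, with 4.37% false calls.

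There were 27 gene lists, and 26 were tested, because none of the 32 transposable element names matched a gene symbol of the annotation. Lists were tested with camera (preset correlation 0.01) and, as an alternative, with an estimated correlation, in 182 tests, adjusted over the 26 lists of each comparison. In 24 tests 8 lists were called, of which 8 calls held with an estimated correlation and 16 did not. The other 18 lists were called in no comparison (lowest adjusted p = 0.053). Overlap of lists with the genes called in all 4 comparisons was tested with Fisher's exact test. List counts are given over all genes and adjusted over the list alone.

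The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The list member Rbp9 was already known from the study that used these samples. The rule names su(Hw), RpII15 and Rbp9 in every comparison, then the 8 largest rises and the 8 largest falls among called genes whose groups of arrays do not overlap, then up to 4 called members of each list with the largest change, and the 10 largest rises and falls among genes called in all 4 comparisons. In the report the list part is applied to the lists called in that comparison, in order of size. The effect of the alternatives was computed for all 721 pairs of a called gene and a comparison that the rule names, whether or not the report prints them. Gene order around su(Hw) was used in place of the planned distances and chromosome arms, because the probe annotation names no genome build. It was taken from the gene table of the assembly Release 6 plus ISO1 MT by gene name. This measure was chosen after seeing the data. The test of nervous tissue against f/v replaced a count of list members called lower in the sterile against fertile contrast (6), which rested on falls against wild type, and the chorion test was widened from the 5 genes that fell to all 7 chorion genes of the list.

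Alternatives were values as deposited, subtraction of the array median, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set separately, only the arrays of the groups compared, eBayes with trend and robust settings, array weights, a replicate block, an adjusted p below 0.01, a change of at least 2-fold, and omission of each array. Probe sets with several genes or no symbol were left out of the gene tests.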

Results

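Signal was analysed from 12 expression arrays of ovaries from virgin female flies collected 4 to 6 h after eclosion. The 4 groups of 3 arrays were wild type (Canton S), the fertile su(Hw)f/v genotype and the sterile su(Hw)2/v and su(Hw)Pb/2 genotypes. By their names both sterile genotypes carry the su(Hw)2 allele, which neither fertile group has, and f/v and 2/v share the v allele. Each array came from a pool of about 150 pairs of ovaries, so the p-values below measure a spread between pooled samples that may be largely technical. By the design of the series, egg chambers at this age reach stage 8 at most in every genotype, and cells without Su(Hw) die at stage 9. Array medians lay between 98.4 and 134 intensity units, and 57.8 to 63.6% of the probe sets lay above the 95th percentile of the bacterial control probe sets (61.97), which is called background below. Arrays of the same group correlated at 0.987 to 0.993, and arrays of different groups at 0.943 to 0.980. The hybridization control CreX, added at a fixed amount, read 45879 ± 1211 (SD) in wild type and 56133 ± 2360 in f/v. It read 63747 ± 6719 in 2/v and 65801 ± 7111 in Pb/2. These are 1.22 (f/v), 1.39 (2/v) and 1.43 (Pb/2) times wild type. The controls BioB, BioC and BioDn read 1.19 to 1.23 times wild type in f/v, 1.37 to 1.41 in 2/v and 1.45 to 1.49 in Pb/2. No alternative scaled the arrays to these controls, so how small changes depend on this was not tested. Values after each gene are log2 fold changes between means of 3 arrays per group, and levels are mean normalized signals. The standard error after ± comes from the fit of all 12 arrays, so a gene has the same error in each pair of groups. The folds are on the log2(signal + 16) scale, which understates the change of genes with low signal. The size and rank of genes below background depend on the offset, and ss in f/v against wild type read 8.81 with an offset of 1 and 4.92 with 64. For genes below background in the dimmer of a pair of groups, the brighter group is also given as at least so many fold above the higher of background and the dimmer signal.

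The su(Hw) transcript, which encodes a zinc finger insulator protein, read 3862, 3561 and 3999 in the wild type arrays and 2912, 2708 and 2591 in the f/v arrays. It read 85.1, 129 and 81.4 in the 2/v arrays and 85.8, 153 and 212 in the Pb/2 arrays, so its signal separated all 6 arrays of the sterile genotypes from the 6 others. Against wild type su(Hw) fell in 2/v (-5.08 ± 0.25, adjusted p = 1.5e-07) and in Pb/2 (-4.60 ± 0.25, adjusted p = 3.1e-07), and was not called in f/v (-0.47 ± 0.25, adjusted p = 0.17). All f/v arrays read below all wild type arrays, but this error also holds the spread of the dim sterile arrays. Rbp9, which encodes an RNA-binding protein of the Elav family, read 3583 in wild type, 2665 in f/v, 9170 in 2/v and 8258 in Pb/2. It rose by 1.35 ± 0.11 in 2/v and by 1.21 ± 0.11 in Pb/2, and fell in f/v (-0.43 ± 0.11, adjusted p = 0.013). The call of Rbp9 in f/v turned to 0.05 with the mean of its probe sets and to 0.53 in its other probe set, neither of which passed the test, and missed the threshold with only the arrays of these groups (adjusted p = 0.051, from 0.0021 to 0.79 over its alternatives). The other probe set read 0.03 in 2/v against wild type, where it did not pass the test, and 0.65 in Pb/2. Its mean signal was 82, close to background (61.97), against 5919 for the main probe set. The annotation assigns no probe set to the neighbouring gene RpII15, under this name, its current name Polr2I or its gene number, so the gene was not analysed here. Probe sets with no symbol numbered 4720.

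**Figure D1:**
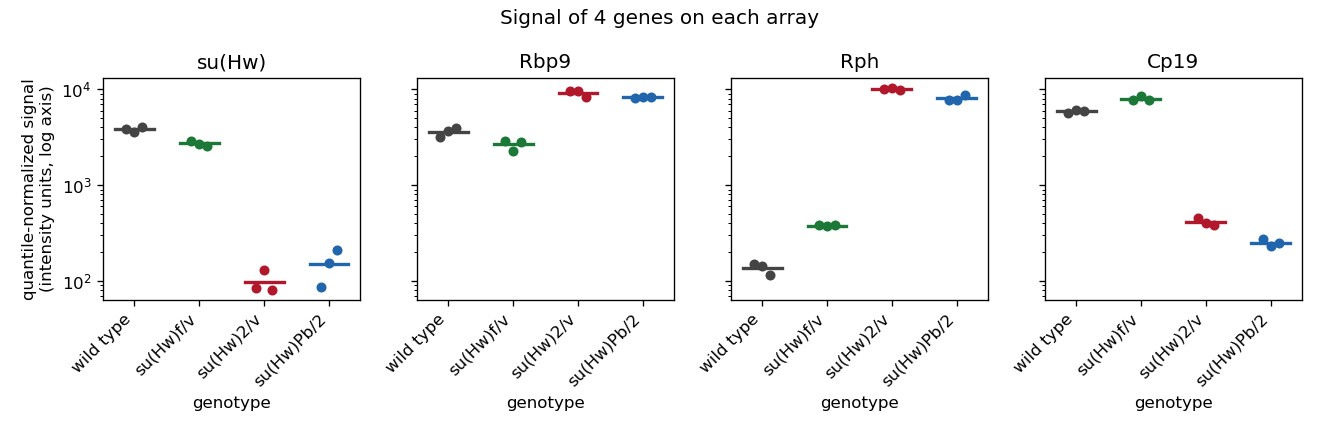
Normalized signal of su(Hw), Rbp9, Rph and Cp19 on each of the 12 arrays, 3 per genotype, with the group mean as a line, on a log axis in intensity units.

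In the fertile f/v ovaries the largest rise against wild type was that of ss, a bHLH-PAS transcription factor, which went from 4 to 1991 (6.66 ± 0.15) and stayed below background in the other 3 groups. It was followed by Elovl7 (5.93 ± 0.14), the polarity gene l(2)gl (5.78 ± 0.21), the germline transcription factor ovo (5.42 ± 0.14, from 121 to 5874), the chorion gene Cp15 (5.23 ± 0.17, from 279 to 11009), the Arp2/3 subunit Arpc1 (5.14 ± 0.11), NFAT (5.06 ± 0.15) and CG16762 (5.03 ± 0.21). Elovl7, l(2)gl and CG16762 lay below background in wild type, and with ss were at least 43.0, 53.9, 31.6 and 32.1-fold higher in f/v. Elovl7, l(2)gl and ovo rose to a similar extent in both sterile genotypes, so they set wild type apart from all 3 mutants. Strain sequence differences under the probes could account for such genes. The largest falls were those of CG42565 (-7.13 ± 0.17, from 8225 to 44), CG4210 (-5.72 ± 0.38), CG14275 (-5.51 ± 0.16), CG34227 (-5.33 ± 0.49), Bace (-5.17 ± 0.27), GstZ1 (-5.11 ± 0.21), Zip102B (-4.89 ± 0.32) and the trypsin gene alphaTry (-4.84 ± 0.19). CG42565, CG4210, CG34227 and Bace lay below background in f/v, where they were at least 133, 26.2, 27.2 and 29.6-fold lower.

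Of 19 gut genes 14 fell and 2 rose in f/v, with the same counts adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.012 with an estimated correlation). Among them were the proteases alphaTry, Jon65Aiii (-4.19 ± 0.20) and betaTry (-3.88 ± 0.41, at least 11.5-fold) and the maltase Mal-A1 (-2.99 ± 0.13). Of 22 muscle genes 16 fell and 1 rose, also when adjusted over the list alone (adjusted p = 2.2e-08, and adjusted p = 0.018 with an estimated correlation). The troponin C gene TpnC41C fell by 1.78 ± 0.23 on the log2 scale, and the sarcomere genes sls by 1.40 ± 0.17, Obsc by 1.36 ± 0.10 and bt by 1.23 ± 0.14. Of 18 follicle cell and somatic gonad genes 10 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation). They included the transcription factor genes ct (-1.18 ± 0.29), zfh1 (-1.05 ± 0.15), cas (-1.0 ± 0.19) and mirr (-0.92 ± 0.10). CreX read 1.22 times wild type in the same arrays. The calls of mirr and sls ended when every probe set was tested separately. Whether the gut and muscle genes changed within the ovary, or other tissue in the dissected samples differed between the groups, was not tested.

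In all, 3209 of 9105 genes were called in f/v against wild type, 1668 higher and 1541 lower, and 742 of them changed at least 2-fold. The arrays of the groups did not overlap for 4533 genes (49.8%, where 10% is the share by chance). Values as deposited gave 1339 higher and 1901 lower, and subtraction of the array median gave 2360 higher and 1146 lower. Subtraction of the array median moved the median of all genes by more than 0.1 in f/v (0.16), 2/v (0.21) and Pb/2 (0.17) against wild type and in the sterile against fertile contrast (0.11).

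In the sterile 2/v ovaries the largest rise against wild type was that of Rph, the gene of the synaptic vesicle protein rabphilin, from 136 to 10004 (6.05 ± 0.09). Elovl7 (6.03 ± 0.14), l(2)gl (5.92 ± 0.21), CG4570 (5.46 ± 0.16), CG15760 (5.42 ± 0.15), CG42857 (5.31 ± 0.14), ovo (5.26 ± 0.14) and CG1695 (5.26 ± 0.15) came next, and all but Rph, CG42857 and ovo lay below background in wild type. The bounds were at least 46.1-fold for Elovl7, 59.5 for l(2)gl, 45.5 for CG4570, 28.9 for CG15760 and 44.2 for CG1695. The largest falls were those of CG4210 (-5.62 ± 0.38), CG34227 (-5.45 ± 0.49), su(Hw), the neuropeptide-like gene Nplp3 (-4.60 ± 0.23, from 1466 to 48), CG42565 (-4.59 ± 0.17), Bace (-4.51 ± 0.27), CG15571 (-4.46 ± 0.28) and Jon65Aiii (-4.45 ± 0.20). CG4210, CG34227, Nplp3 and CG15571 lay below background in 2/v, where they were at least 26.2, 24.1, 22.1 and 12.7-fold lower.

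Of the gut genes 13 fell and 2 rose in 2/v, also when adjusted over the list alone (adjusted p = 3.8e-05, and adjusted p = 0.024 with an estimated correlation), with Jon65Aiii, betaTry (-3.68 ± 0.41), alphaTry (-3.43 ± 0.19) and Jon65Aii (-2.84 ± 0.15) at the head. In 2/v betaTry and Jon65Aii lay below background (at least 11.6 and 2.23-fold lower), as did TpnC41C (4.09) of the muscle genes and eater (3.19) of the hemocyte genes below. Of the muscle genes 17 fell and 2 rose, also when adjusted over the list alone (adjusted p = 1.1e-07, and adjusted p = 0.024 with an estimated correlation), led by TpnC41C (-2.08 ± 0.23), sls (-2.0 ± 0.17), bt (-1.84 ± 0.14) and the myosin light chain gene Mlc2 (-1.55 ± 0.07). CreX read 1.39 times wild type in these arrays. Of 18 follicle cell genes 11 fell and 2 rose, also when adjusted over the list alone (adjusted p = 0.0079, and adjusted p = 0.29 with an estimated correlation), with ct (-1.69 ± 0.29), cas (-1.64 ± 0.19) and mirr (-1.54 ± 0.10) lowest.

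Of 20 hemocyte and basement membrane genes 12 fell and 2 rose in 2/v, or 13 and 2 adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.13 with an estimated correlation). The phagocytosis receptor genes NimC1 and eater fell by 2.07 ± 0.14 and 1.97 ± 0.31 on the log2 scale, the matrix gene Ppn by 1.43 ± 0.07 and Hml by 1.36 ± 0.49. Of 9 heat shock and stress genes 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.29 with an estimated correlation), and with the array median subtracted the median of the list went from -0.25 to 0.17 and its mean from -0.24 to 0.11. TotC, a stress-induced secreted protein gene, rose by 2.08 ± 0.18, while the chaperone genes stv, Hsp68 and DnaJ-1 fell (-1.21 ± 0.18, -1.11 ± 0.13 and -0.80 ± 0.07). The call of Hml ended under several alternatives, the omission of each wild type array among them.

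In all, 4239 genes were called in 2/v against wild type, 2201 higher and 2038 lower, and 977 of them changed at least 2-fold. The groups did not overlap for 5192 genes (57.0%, where 10% is the share by chance). Values as deposited gave 1929 higher and 2639 lower, and subtraction of the array median gave 3400 higher and 1347 lower.

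In the sterile Pb/2 ovaries l(2)gl (6.30 ± 0.21), Elovl7 (5.97 ± 0.14), Rph (5.74 ± 0.09, from 136 to 8079) and the cytochrome P450 gene Cyp4p2 (5.61 ± 0.31, from 18 to 1555) rose most against wild type. CG1695 (5.38 ± 0.15), ovo (5.27 ± 0.14), NFAT (5.07 ± 0.15) and the calcineurin subunit gene CanB (5.04 ± 0.13) came next, and l(2)gl, Elovl7, Cyp4p2 and CG1695 lay below background in wild type and were at least 77.3, 44.2, 25.0 and 48.0-fold higher. The largest falls were those of CG8997 (-5.54 ± 0.16), the zinc transporter gene Zip102B (-4.71 ± 0.32), su(Hw), CG4363 (-4.57 ± 0.36), CG12374 (-4.57 ± 0.14), CG34227 (-4.52 ± 0.49), the chorion gene Cp19 (-4.47 ± 0.09, from 5912 to 251) and Nplp3 (-4.47 ± 0.23). CG8997, CG4363, CG12374, CG34227 and Nplp3 lay below background in Pb/2, where they were at least 17.9, 14.6, 8.43, 25.8 and 23.4-fold lower.

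Of the gut genes 14 fell and 1 rose in Pb/2, or 15 and 1 adjusted over the list alone (adjusted p = 9.5e-09, and adjusted p = 0.0046 with an estimated correlation), led by alphaTry (-3.71 ± 0.19), Jon99Ci (-3.29 ± 0.30), Mal-A1 (-3.16 ± 0.13) and Jon65Aiii (-3.07 ± 0.20). Of the muscle genes 16 fell and 1 rose, also when adjusted over the list alone (adjusted p = 5.3e-09, and adjusted p = 0.015 with an estimated correlation), led by TpnC41C (-1.98 ± 0.23), sls (-1.47 ± 0.17), tn (-1.44 ± 0.10) and Obsc (-1.37 ± 0.10). CreX read 1.43 times wild type in these arrays. Of the hemocyte and basement membrane genes 8 fell and 1 rose, or 13 and 2 adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.24 with an estimated correlation), with NimC1 (-1.92 ± 0.14), Hml (-1.58 ± 0.49) and eater (-1.55 ± 0.31) lower and lz (1.23 ± 0.21) higher. Of the heat shock and stress genes 6 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0052, and adjusted p = 0.23 with an estimated correlation). Hsp68 (-1.61 ± 0.13), stv (-1.45 ± 0.18) and DnaJ-1 (-1.0 ± 0.07) were lower and TotC (1.38 ± 0.18) higher. With the array median subtracted the median of the list went from -0.33 to -0.01 and its mean from -0.49 to -0.20. TpnC41C, Jon99Ci and eater lay below background in Pb/2 (at least 4.06, 5.55 and 2.83-fold lower), and lz in wild type (at least 2.38-fold higher). The call of sls ended with every probe set tested separately, and that of Hml when single arrays were left out.

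In all, 2869 genes were called in Pb/2 against wild type, 1445 higher and 1424 lower, and 926 of them changed at least 2-fold. The groups did not overlap for 4138 genes (45.5%, where 10% is the share by chance). Values as deposited gave 1272 higher and 1885 lower, and subtraction of the array median gave 2517 higher and 1081 lower.

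**Figure D2:**
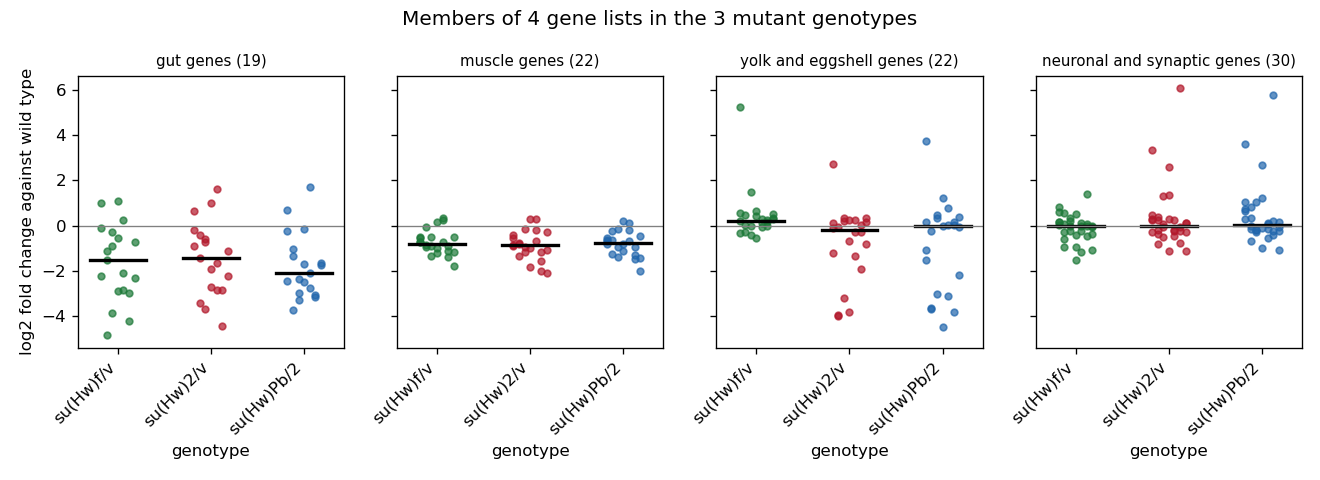
Log2 fold change against wild type of the tested members of 4 gene lists (gut, muscle, yolk and eggshell, neuronal and synaptic) in the 3 mutant genotypes, 3 arrays each, with the list median as a black line. The medians of the gut and muscle lists stayed below 0 in all 3 genotypes under each scaling.

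Set against the fertile f/v ovaries, 2/v ovaries had higher Alp10 (4.73 ± 0.45), Rph (4.67 ± 0.09), CG1695 (4.61 ± 0.15), the glutathione S-transferase gene GstD2 (4.59 ± 0.15, from 251 to 6369), Zip102B (4.56 ± 0.32), CG5111 (4.28 ± 0.38), CG9917 (4.21 ± 0.23) and CG32625 (4.13 ± 0.14). Lowest were ss (-6.50 ± 0.15), the chorion genes Cp18 (-4.69 ± 0.15), Cp16 (-4.44 ± 0.14) and Cp19 (-4.23 ± 0.09), su(Hw) (-4.61 ± 0.25), CG13084 (-4.28 ± 0.34), CG15571 (-4.25 ± 0.28) and CG31928 (-4.03 ± 0.28). Alp10 and CG5111 lay below background in f/v, and ss, CG13084, CG15571 and CG31928 in 2/v. The first 2 were at least 18.1 and 8.96-fold higher in 2/v, and the last 4 at least 32.1, 11.2, 10.9 and 8.29-fold lower. Rbp9 rose by 1.78 ± 0.11, and its other probe set, whose signal was close to background, read -0.50 and did not pass the test.

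Of 22 yolk and eggshell genes 11 fell and 4 rose in 2/v against f/v, or 12 and 4 adjusted over the list alone (adjusted p = 1.8e-04, and adjusted p = 0.22 with an estimated correlation), with Femcoat (-4.01 ± 0.23, at least 16.7-fold) beside the chorion genes above. Of 21 germline and oocyte genes 13 fell and none rose, or 13 and 1 adjusted over the list alone (adjusted p = 0.0083, and adjusted p = 0.29 with an estimated correlation). They were led by exu (-1.05 ± 0.11), tud (-0.85 ± 0.25), tor (-0.63 ± 0.16) and fs(1)N (-0.57 ± 0.10). Of the hemocyte and basement membrane genes 7 fell and none rose, or 8 and none adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.29 with an estimated correlation), among them NimC1 (-1.70 ± 0.14) and eater (-1.48 ± 0.31, below background in 2/v and at least 2.20-fold lower). In all, 2494 genes were called, 1259 higher and 1235 lower, and 535 changed at least 2-fold. Values as deposited gave 1159 higher and 1359 lower, and subtraction of the array median gave 1211 higher and 826 lower. The groups did not overlap for 4001 genes (43.9%, where 10% is the share by chance). The calls of exu, tud and tor each ended under at least 1 alternative.

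In Pb/2 against f/v the largest rises were those of Cyp4p2 (5.22 ± 0.31), CG4210 (4.92 ± 0.38), CG31219 (4.85 ± 0.39), CG1695 (4.73 ± 0.15), Rph (4.36 ± 0.09), nrv3, a sodium pump subunit gene (4.19 ± 0.10, from 981 to 18077), Syn2 (3.86 ± 0.20) and Prx6c (3.70 ± 0.15). The largest falls were those of ss (-6.33 ± 0.15), Cp19 (-4.91 ± 0.09), Cp18 (-4.50 ± 0.15), CG13084 (-4.41 ± 0.34), CG15571 (-4.25 ± 0.28), Tektin-C (-4.23 ± 0.21), Cp16 (-4.15 ± 0.14) and su(Hw) (-4.13 ± 0.25). Cyp4p2, CG4210, CG31219 and Syn2 lay below background in f/v, and ss, CG13084, CG15571 and Tektin-C in Pb/2. The first 4 were at least 25.0, 14.9, 16.1 and 10.4-fold higher in Pb/2, and the last 4 at least 32.1, 11.2, 10.9 and 8.53-fold lower. Rbp9 rose by 1.64 ± 0.11.

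Of the yolk and eggshell genes 10 fell and 6 rose in Pb/2 against f/v, or 11 and 7 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.38 with an estimated correlation), with Cp38 (-3.99 ± 0.25) beside the chorion genes above. Of 26 piRNA pathway genes 10 rose and none fell, or 13 and 2 adjusted over the list alone (adjusted p = 0.0048, and adjusted p = 0.38 with an estimated correlation). They were led by tej (0.60 ± 0.07), qin (0.58 ± 0.18), cuff (0.50 ± 0.07) and armi (0.50 ± 0.08). Of the heat shock and stress genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.046, and adjusted p = 0.38 with an estimated correlation), with Hsp68 (-1.09 ± 0.13) and Hsp26 (-0.89 ± 0.08) lower and TotC (2.38 ± 0.18, below background in f/v and at least 5.67-fold higher in Pb/2) higher. In all, 1871 genes were called, 914 higher and 957 lower, and 440 changed at least 2-fold. Values as deposited gave 875 higher and 949 lower, and subtraction of the array median gave 820 higher and 586 lower. The groups did not overlap for 3458 genes (38.0%, where 10% is the share by chance). The call of qin ended under several alternatives, and that of the heat shock list with the replicate block (adjusted p = 0.061).

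The sterile genotypes also differed from each other. Cyp4p2 (5.04 ± 0.31), CG31219 (4.93 ± 0.39), CG4210 (4.82 ± 0.38), CG13032 (4.11 ± 0.30), Obp69a (3.09 ± 0.21), the hormone receptor gene Dh44-R2 (2.71 ± 0.15), CG18545 (2.67 ± 0.13) and Gyc89Da (2.60 ± 0.31) were higher in Pb/2 than in 2/v. Tektin-C (-4.67 ± 0.21), Zip102B (-4.38 ± 0.32), Alp10 (-4.34 ± 0.45), the ribosomal protein gene RpS10a (-3.64 ± 0.13, from 3210 to 243), CG8997 (-3.37 ± 0.16), CG16826 (-3.37 ± 0.33), whe (-2.89 ± 0.25) and obst-H (-2.74 ± 0.41) were lower. Cyp4p2, CG31219, CG4210, CG13032, Obp69a and Gyc89Da lay below background in 2/v, and Tektin-C, Alp10, CG8997, CG16826 and obst-H in Pb/2. The bounds were at least 25.0, 16.1, 14.9, 11.2, 9.31 and 5.47-fold higher for the first 6, and 11.7, 18.9, 3.80, 10.1 and 4.15-fold lower for the last 5. su(Hw) (0.48 ± 0.25, adjusted p = 0.20) and Rbp9 (-0.15 ± 0.11, adjusted p = 0.37) were not called.

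Of the germline and oocyte genes 7 rose and none fell in Pb/2 against 2/v, also when adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.60 with an estimated correlation). They were led by tud (1.15 ± 0.25), exu (0.44 ± 0.11), spn-E (0.40 ± 0.08) and stau (0.37 ± 0.11). The value of exu turned to -0.16 when every probe set was tested separately, and the call of stau ended under at least 1 alternative. In all, 1859 genes were called, 845 higher and 1014 lower, and 208 changed at least 2-fold. The groups did not overlap for 3538 genes (38.9%, where 10% is the share by chance). The count fell to 1155 with the array median subtracted, to 1001 with only the arrays of these groups, and to 997 without 2/v replicate 1.

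With the sterile genotypes averaged and set against the average of the fertile groups, Rph (5.20 ± 0.06), CG1695 (5.0 ± 0.11), CG15760 (4.36 ± 0.10), GstD2 (4.16 ± 0.11), CG42857 (4.02 ± 0.10), CG13928 (3.99 ± 0.10), the peroxiredoxin gene Prx6c (3.76 ± 0.11), Cyp6a17 (3.63 ± 0.14), nrv3 (3.39 ± 0.07) and the kinase activator gene Mob2 (3.24 ± 0.07) rose most among the genes called in all 4 sterile against fertile comparisons. su(Hw) (-4.61 ± 0.18), CG15571 (-4.36 ± 0.20), Cp19 (-4.35 ± 0.06), CG13084 (-4.23 ± 0.24), Cp16 (-4.05 ± 0.10), Cp18 (-3.85 ± 0.11), Femcoat (-3.83 ± 0.16), Nplp3 (-3.60 ± 0.16), CG13083 (-3.51 ± 0.17) and CG13113 (-3.38 ± 0.23) fell most. The other probe set of Mob2 read 0.45 in the contrast, and -0.01 in 2/v and 0.09 in Pb/2 against wild type. CG1695 and CG15760 lay below background in wild type, Cyp6a17 in both fertile groups, and CG15571, CG13084, Nplp3 and CG13113 in both sterile genotypes. Against wild type, 2/v was at least 44.2, 28.9 and 12.3-fold higher for the first 3 and 12.7, 9.56, 22.1 and 6.66-fold lower for the last 4. Femcoat lay below background in 2/v and was at least 16.4-fold lower there than in wild type.

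**Figure D3:**
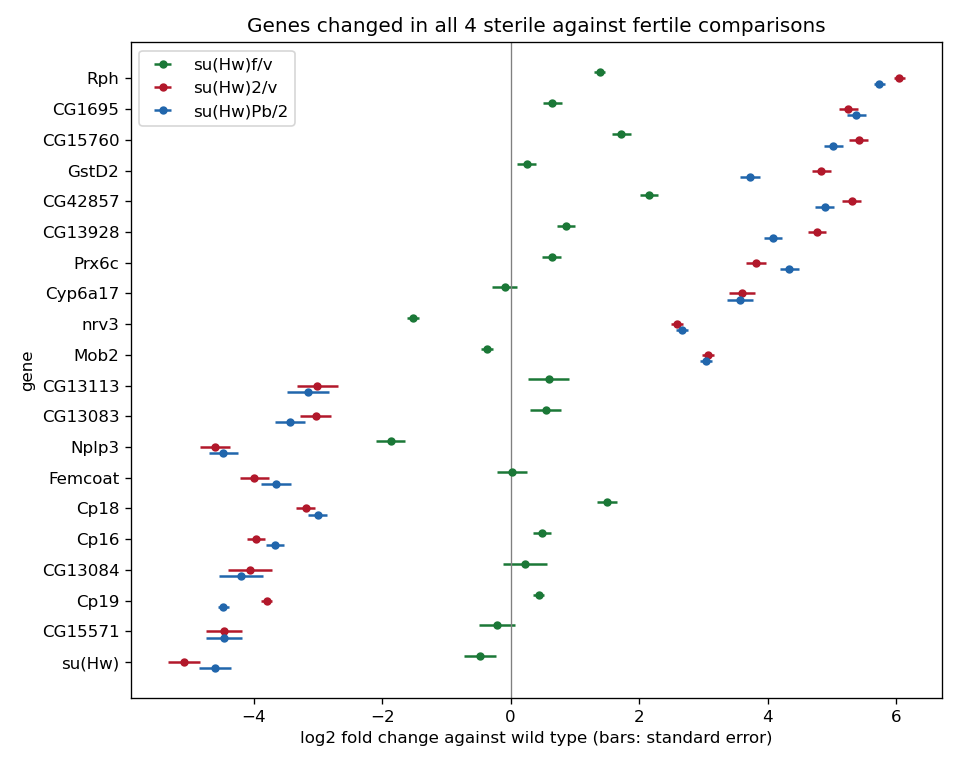
Log2 fold change against wild type (3 arrays per genotype, bars: standard error) of the 10 largest rises and 10 largest falls among genes called the same way in all 4 sterile against fertile comparisons. Values and ranks of genes below background in a group depend on the offset of 16.

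Of 30 neuronal and synaptic genes 5 rose in all 4 comparisons, where 0.916 were expected: Rph, nrv3, the neuroligin gene Nlg2 (3.05 ± 0.19), Rbp9 (1.49 ± 0.08) and the synaptobrevin gene nSyb (Fisher's exact test, adjusted p = 0.025). Rbp9 was already known from the study that used these samples, so it is not an independent hit, and the test was not run without it. The list as a whole was not called (8 rose and 6 fell, or 9 and 6 adjusted over the list alone, adjusted p = 0.42). Against f/v 5 of its genes rose and 2 fell in 2/v (adjusted p = 0.51), and 7 rose and 3 fell in Pb/2 (adjusted p = 0.053, and adjusted p = 0.38 with an estimated correlation). The gene elav, a marker of neurons, fell against wild type in f/v, 2/v and Pb/2 (-1.09, -1.10 and -1.08). Nlg2 lay below background in wild type and was at least 7.92-fold higher in 2/v and 9.45-fold higher in Pb/2. nSyb lay below background in both fertile groups, and against either was at least 1.86-fold higher in 2/v and 1.55-fold higher in Pb/2. The elav signal was not called against f/v in 2/v (-0.01) or Pb/2 (0.01). The genes nSyb and elav, and the members of the counts that follow where the rule does not name them, were chosen after their values were seen. The calls of Nlg2 and Rbp9 ended when every probe set was tested separately, and their other probe sets read 0.45 and 0.07 in the contrast. These other probe sets had mean signals of 94 and 82, close to background (61.97), against 304 and 5919 for the main ones, so they say little on the rise. Of the yolk and eggshell genes 8 fell in all 4 comparisons, namely Cp16, Cp18, Cp19, Cp36, Cp38, yellow-g, Fcp3C and Femcoat (adjusted p = 1.7e-06), and 1, Vm26Aa, rose in all 4 (0.39 ± 0.06). Cp15 rose against wild type (2.70 in 2/v and 3.71 in Pb/2) and fell against f/v (-2.53 and -1.52), and Cp7Fc was not called in any of the 4 (0.17, -0.06, -0.16 and -0.39). Of 15 fat body genes 4 fell in all 4 (Lsp2, Fbp1, Fbp2 and fat-spondin, adjusted p = 0.011). The gene fit, below background in wild type, rose in all 4 (1.71 ± 0.18) and was at least 3.29-fold higher in 2/v and 3.37-fold higher in Pb/2 than in wild type. The list as a whole was not called (3 rose and 7 fell, or 5 and 7 adjusted over the list alone, median 0.04, adjusted p = 0.42). Of the heat shock genes 3 fell in all 4 (Hsp26, Hsp68 and DnaJ-1, adjusted p = 0.020), while TotC rose in all 4.

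In the sterile against fertile contrast 13 gut genes fell and 1 rose, also when adjusted over the list alone (adjusted p = 9.0e-06, and adjusted p = 0.019 with an estimated correlation), with Jon99Fi (-1.94 ± 0.10) and Jon99Ci (-1.81 ± 0.21) lowest. Of the muscle genes 15 fell and 1 rose, or 17 and 1 adjusted over the list alone (adjusted p = 6.6e-07, and adjusted p = 0.033 with an estimated correlation), led by TpnC41C (-1.14 ± 0.16) and sls (-1.03 ± 0.12). Neither list was called against f/v alone, so both calls rest on the difference between wild type and the 3 mutant genotypes. Other tissue in the dissected samples was not tested as a source of it. The gut list had a median of -1.52 in f/v against wild type. Against f/v it had 3 genes higher and 1 lower in 2/v (median 0.07, adjusted p = 0.71) and 5 higher and 5 lower in Pb/2 (median -0.01, adjusted p = 0.75). The muscle list had a median of -0.80 in f/v against wild type. Against f/v, 4 of its genes fell in 2/v, or 3 adjusted over the list alone (median -0.05, adjusted p = 0.51), and 1 in Pb/2 (median -0.04, adjusted p = 0.81). Of the hemocyte genes 11 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0041, and adjusted p = 0.15 with an estimated correlation), led by NimC1 (-1.81 ± 0.10) and eater (-1.51 ± 0.22). Of the heat shock genes 7 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0079, and adjusted p = 0.22 with an estimated correlation), and with the array median subtracted their median went from -0.20 to -0.03 and their mean from -0.19 to 0.01. TotC (2.23 ± 0.13) rose and Hsp68 (-1.10 ± 0.09) fell. Of these genes TpnC41C and eater lay below background in both sterile genotypes, Jon99Fi in 2/v, Jon99Ci in Pb/2 and TotC in f/v. TpnC41C was at least 4.09-fold lower and Jon99Fi at least 3.89-fold lower in 2/v than in wild type. Jon99Ci was at least 4.57-fold lower in Pb/2 than in f/v, eater at least 2.20-fold lower and TotC at least 9.41-fold higher in 2/v than in f/v. Of the yolk and eggshell genes 9 fell and 7 rose, also when adjusted over the list alone (adjusted p = 0.037, and adjusted p = 0.38 with an estimated correlation), and with the array median subtracted their median went from -0.11 to 0.03 and their mean from -1.05 to -0.91.

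The contrast called 3339 genes, 1687 higher and 1652 lower, and 507 of them changed at least 2-fold. The groups of 6 arrays did not overlap for 831 genes (9.13%). The share by chance would be 0.2165% if all arrays were exchangeable. They are not, since each side joins whole genotypes whose arrays are alike, and differences between single genotypes can also separate the sides. The excess over 0.2165% therefore says nothing on how the genotypes pair. Values as deposited gave 1541 higher and 2103 lower, and subtraction of the array median gave 2698 higher and 1101 lower. The same way in all 4 comparisons were 507 genes, 278 higher and 229 lower, against 233 higher and 275 lower with values as deposited and 301 higher and 147 lower with the array median subtracted. Of the 278 higher genes f/v was called higher than wild type for 88, lower for 38 and neither for 152. Of the 229 lower genes f/v was called lower for 68, higher for 27 and neither for 134. Against wild type 792 genes were higher and 760 lower in all 3 mutant genotypes.

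**Figure D4:**
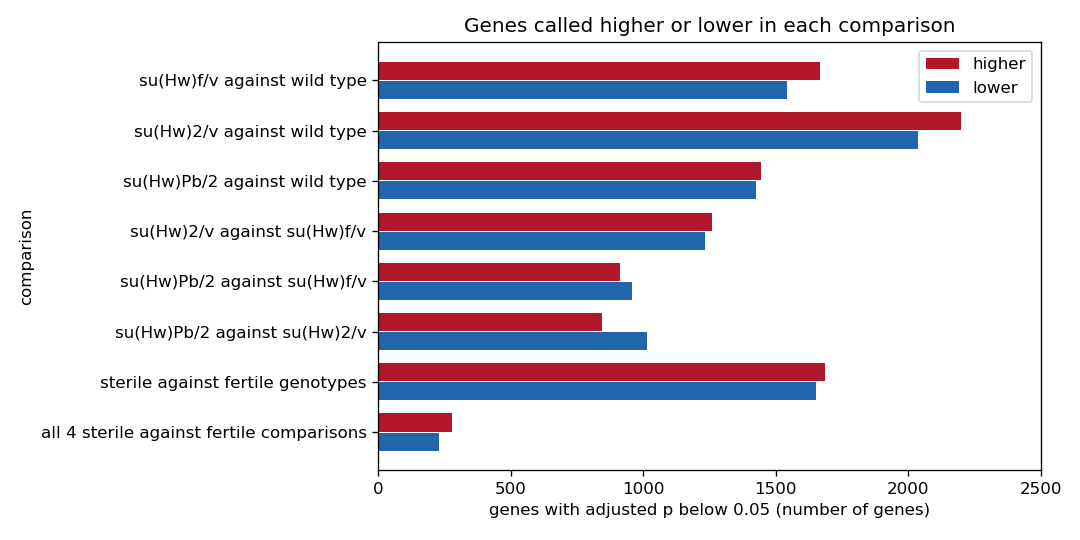
Number of the 9105 tested genes called higher or lower (adjusted p below 0.05) in each comparison of groups of 3 arrays, in the contrast of 6 sterile against 6 fertile arrays, and in all 4 sterile against fertile comparisons. The share of higher calls among all calls moved by more than 10 points with the array median subtracted in the 3 comparisons with wild type, in the contrast and in the set of all 4.

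Comparisons that used no array in common were correlated. The change in 2/v against f/v correlated at 0.269 (Spearman 0.211) with that in Pb/2 against wild type (covariance 0.113), with 458 genes higher in both where 200 were expected, 378 lower in both where 193 were expected, and 391 opposite. The change in 2/v against wild type correlated at 0.276 (Spearman 0.109) with that in Pb/2 against f/v (covariance 0.113), with 405 higher in both (expected 221), 352 lower in both (expected 214) and 414 opposite.

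Where the comparisons used the same control arrays, part of the excess may come from the shared controls, since 3 arrays cannot be split into 2 sets of at least 2. The correlations were 0.685 for f/v and 2/v against wild type (simulated 0.50, covariance 0.349 against 0.0173), 0.704 for f/v and Pb/2 (simulated 0.50, covariance 0.349 against 0.0174), 0.838 for 2/v and Pb/2 (simulated 0.501, covariance 0.461 against 0.0174) and 0.713 for 2/v and Pb/2 against f/v (simulated 0.50, covariance 0.222 against 0.0173). Genes higher and lower in both numbered 1122 and 1047 (expected 403 and 345), 920 and 895 (265 and 241), 1154 and 1070 (349 and 319), and 592 and 514 (126 and 130). For the sets of all 4 and of all 3 comparisons, simulated data gave 0 genes, and independent calls would give 5 and 5, and 64 and 54.

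No excess of called genes near su(Hw) passed the test. Gene order was taken from the gene table of the assembly Release 6 plus ISO1 MT by gene name, and distances were not used, since the probe annotation names no build. The share of called genes among the 50, 100 and 250 tested genes on each side of su(Hw), whose nearest tested neighbours are IFT54 and Set8, was compared with that of the other genes in 30 tests (lowest adjusted p = 0.88).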

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

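The tests of scaling, strain probe differences, linkage and other splits of the arrays were planned before the result was seen, though linkage was measured in gene order, a measure chosen after the data were seen, and the tests of nervous tissue, of the share and number of late egg chambers, of the parts of the scaling test and of the pairings of whole genotypes were chosen after the result was seen.

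Between the sterile genotypes 1859 genes differed by a test of the difference itself. Called one way in f/v and the other way in both sterile genotypes against both fertile groups were 65 genes, nrv3, Cp16, Cp18 and Cp19 among them. They were 38 of the 278 higher and 27 of the 229 lower genes. Over all 9105 genes f/v was called lower than wild type for 1541 and higher for 1668, which are larger shares. The number of opposite genes is therefore no excess. Outside the gene tests, 276 probe sets with no gene name were called in the sterile against fertile contrast. The hybridization control CreX read 1.223 times wild type in f/v, 1.389 times in 2/v and 1.434 times in Pb/2.

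Neuronal genes (Rph, nrv3, Nlg2, Rbp9 and nSyb) rose in both sterile genotypes. Nervous tissue carried into the samples would raise the whole list, but its medians against f/v were 0.0669 in 2/v (95% bootstrap interval -0.1772 to 0.19) and 0.1977 in Pb/2 (-0.0726 to 0.4794, and up to 0.4883 under the other scalings, 7 genes higher and 3 lower, adjusted p = 0.053) and elav read 382 in f/v, 374 in 2/v and 379 in Pb/2, which argues against it as the whole cause (a small share stays open). A lower share of late egg chambers that raised all other transcripts alike would raise the germline and oocyte list, if late chambers hold little of it. Rbp9 rose by 1.49, while the median of that list was -0.0625 (95% bootstrap interval -0.1294 to -0.0079), and 0.1538 (-0.0081 to 0.2369) with the array median subtracted. The list did not rise as Rbp9 did under any scaling. Late chambers may hold transcripts of this list too, so the test cannot tell whether their share was lower. The scaling test planned before the result asked that all 5 genes keep their calls under both other scalings, and 4 did: in Pb/2 against wild type nSyb, below background in both fertile groups and at least 1.55-fold higher, went from 1.06 ± 0.30 (adjusted p = 0.022) to 0.941 ± 0.34 with values as deposited (adjusted p = 0.052, and 0.011 with the array median subtracted), so its call ended on a slightly lower fold and a larger error. The test was split only after the result was seen, so that Rbp9, Rph, nrv3 and Nlg2 kept their calls (4) was known and is no separate test. It shows only that the calls of these 4 genes do not depend on which of the scalings is used. For nSyb it could not be told (0.941), and the genotype itself stays open, untested.

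Chorion and other eggshell genes fell in both sterile genotypes. Fewer late egg chambers in the sterile samples could be neither shown nor excluded. The 5 chorion genes that fell in each comparison (-1.33 to -4.91 on the log2 scale) were chosen by their fall, and Cp7Fc was called in none. Cp15 rose against wild type in f/v as in both sterile genotypes, and against f/v it fell in both, like the 5 genes. The median of 8 yolk and vitelline membrane genes was 0.2602 (95% bootstrap interval -0.0045 to 0.4071). By the design no genotype has chambers past stage 8 at this age, and no egg chamber was counted. Scaling of the arrays is argued against, since all 8 genes kept their calls under both other scalings. The genotype itself stays open, untested.

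At least 4-fold apart between wild type and all 3 mutants, the same way, were 88 genes, 43 higher and 45 lower, with Elovl7, l(2)gl and ovo among the higher ones. Strain sequence differences under the probes could account for them, and the test could not tell: 50% of the other probe sets of these genes differed at least 2-fold the same way (4 of 8), against 0 of 3 for the comparison set (Fisher's exact test p = 0.24), and 5 of 8 and 2 of 3 had the same sign. Gathering of these genes close to su(Hw) is argued against, since 2.273% of them lay among the 100 nearest tested genes on each side. These 200 genes are a small part of the 2241 tested genes on the same chromosome sequence as su(Hw). Linkage beyond the 250 nearest genes on each side was not tested and stays open.

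The 10 splits of 6 arrays cannot give a share under 0.05. Every split but the real one mixes arrays of 2 genotypes, whose difference widens the spread, so few calls were bound to follow and the counts settle nothing. The real split and the highest other called 3209 and 1 genes in f/v against wild type, 4239 and 0 in 2/v, 2869 and 0 in Pb/2, 2494 and 0 in 2/v against f/v, 1871 and 1 in Pb/2 against f/v, and 1859 and 0 in Pb/2 against 2/v. In a fit of 2 groups the sterile against fertile split called 1402 genes and the highest of the other drawn splits 1, so 1 of 100 was as large. For genes called in all 4 comparisons the values were 507 and 8, and 1 of 100 regroupings was as large. The drawn splits and regroupings broke up the genotypes, whose differences widened the spread, so few calls were bound to follow. They therefore say nothing on how genotypes pair. With whole genotypes paired otherwise, f/v and 2/v against wild type and Pb/2 gave 853 genes and 178 in all 4, and f/v and Pb/2 against wild type and 2/v gave 355 and 199, so part of such counts arises with any pairing.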

How the results depend on the processing

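All alternatives here were chosen before the data were examined. Of 207 alternative values of the 8 gene counts 187 stayed within 1.5 times the main count. A 2-fold threshold gave 742 (f/v), 977 (2/v) and 926 (Pb/2 against wild type), 535 and 440 (2/v and Pb/2 against f/v), 208 (Pb/2 against 2/v), 507 (sterile against fertile) and 152 (all 4), and an adjusted p below 0.01 gave 2029, 1858 (Pb/2), 1399, 996, 648, 2149 and 283, both by construction. The count in Pb/2 against 2/v was 1155 with the array median subtracted, 1001 with only the arrays compared, and 997 to 1857 in leave-one-out fits (997 without 2/v replicate 1, 1028 and 1110 without Pb/2 replicates 1 and 2), and the cause was not tested. The correlations of 0.269 and 0.276 became 0.2387 and 0.2422 with no filter, and the first 0.2959 with the 60th percentile filter. Of the 721 named gene results 189 changed their call in at least 1 alternative, 130 of them when single arrays were left out, and of 17011 alternative values 16003 were the same, 993 no longer passed the test and 15 reversed. The 60th percentile filter kept 597 of these results and all 597 were the same, and it left out genes of lower signal. With the replicate block 67 of the 721 lost their call. Reversed with the mean of all probe sets were Rbp9 (0.0527) and mod(mdg4) (0.0281) in f/v against wild type and cpx (0.0365) in Pb/2 against 2/v. Reversed with every probe set separately were Rbp9 (0.5344), mod(mdg4) (0.8159) and pum (0.0799) in f/v against wild type, Rbp9 (-0.5038) and mod(mdg4) (-1.8743) in 2/v against f/v, mod(mdg4) (-2.0917) and pum (-0.2253) in Pb/2 against f/v, futsch (-0.5585), cpx (0.5) and exu (-0.1626) in Pb/2 against 2/v, and mod(mdg4) (-2.2459) in the contrast. The other probe set of Rbp9 had a mean signal of 82, close to background (61.97), against 5919 for the main one. RpL28 reversed in f/v against wild type with the array median subtracted (0.098). Of the gene list tests 16 lost their call with an estimated correlation and 1 with the replicate block, and the fry test gained 90 calls and reversed the germline differentiation list in f/v and 2/v against wild type (0.005256 and 0.0007473). The causes were not tested.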

Other observations

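The value below was chosen after its values were seen. mod(mdg4), a gene with many transcript forms, has 22 probe sets, of which 12 were called higher, 2 lower and 8 neither in the sterile against fertile contrast. Its main probe set rose by 0.41 ± 0.05, and another fell by 2.25 on the log2 scale.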
